A study of Mus musculus with 35 samples.

How the data were processed

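Messenger RNA and ribosome-protected fragments were measured in mouse acute myeloid leukemia cells carrying the MLL-AF9 fusion. Per the labels' protocols, male recipient mice were injected with leukemia cells, and the GFP-positive cells were sorted from bone marrow after lysis of red blood cells. Each library came from 1 mouse. From a lysate of 20 µl, 2 µl went into Smart-seq2, a full-length mRNA protocol that keeps no strand and uses no molecular identifiers. The rest was digested with RNase I and spun through sucrose to collect ribosomes, whose footprints were sequenced. The labels give the same replicate number to the RNA and footprint library of 1 mouse, and 12 mice had both.

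The deposited files hold raw counts of reads per Ensembl gene, 1 column per library, as the authors made them. Per the submitters' processing notes, cutadapt, Bowtie2, STAR, SAMtools and featureCounts were used with the builds GRCm38 and mm10. Versions, the order of steps, the annotation release, the strand setting and the treatment of multiply mapped reads were not given in the sources used here. Every deposited column matched 1 sample. Of the 55487 genes listed, 55141 were named through GENCODE, and 346 kept only their identifier. Coordinates, gene types and coding lengths came from a GRCm38 annotation.

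How the counting treats shared reads matters most for the footprints, which are short. Pseudogenes took 26.4% of all footprint counts against 0.333% of RNA counts. Counts of pseudogenes, of paralogs such as Cyp2a5 and Cyp2a4, the globins, the Stfa and Ifit families and histone genes, and of overlapping or antisense genes may therefore hold reads of another gene. Their values are given as uncertain. The intervals and floors below cover counting error only, since PCR copies were not told apart.

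Total counts ran from 31.9 to 142.7 M (mega) over 23 RNA libraries, with a median of 56.1 M, and from 5.7 to 14.6 M over 12 footprint libraries, with a median of 9.25 M. The biological coefficient of variation was 0.494 in RNA and 0.156 in footprints. An alternative without shallow libraries, those far below the median total of their assay, removed 0 libraries. Replicates were checked for double deposits. The smallest chi-square per degree of freedom was 19.6 over 56 RNA pairs and 6.84 over 13 footprint pairs, so no pair agreed within sampling noise. Each footprint library correlated better with the RNA of its own mouse than with that of any other mouse of its group, with r from 0.177 to 0.605 over 7592 genes in groups of 3 or more, after group means were removed. In the group of 2 mice removing the mean makes them mirror images, so only the sign of r = 0.683 is informative there. The pairing of RNA and footprints within a mouse comes from the labels.

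Gene tests used edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with trimmed mean of M values (TMM) scaling, the filterByExpr filter and the robust quasi-likelihood test. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. All 4 groups of an assay shared 1 fit, with 19 residual degrees of freedom in RNA and 8 in footprints. Contrasts were the effect of treatment in each genotype, the effect of genotype in each treatment, and the interaction, that is, the treatment effect in sgOgfod1 cells minus that in sgScramble cells. Translation efficiency, meaning footprints relative to mRNA, was tested as the assay-by-group term of 1 model over both assays of the 12 mice, with the mouse as a block and 8 residual degrees of freedom. Standard errors of log2 fold changes were derived from the quasi-likelihood statistic. Levels are given as CPM on TMM-scaled library sizes, with the standard deviation (SD) over mice. The number of libraries in a direction counts libraries of the treated group, or of the sgOgfod1 group in genotype contrasts, beyond the median of the other group.

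Ogfod1 was tested in every comparison, and its range on leaving out libraries is given for each. Each comparison also named, by a fixed rule, up to 8 genes up and 8 down with the largest log2 fold change. They had to pass the threshold, reach a mean of 10 CPM in the higher group, and have every library of the higher group above the median of the lower. For translation efficiency the minimum applied to footprint CPM and the direction to the footprint-to-RNA ratio of each mouse. For genes that this rule named as higher, a full count of libraries in the direction was thus fixed by selection. Such counts add no support for them. Predicted, Riken and Gm genes and pseudogenes were skipped. Of each gene list, up to 4 members with the smallest p could be named. There were 36 lists, covering pathways, cell states and markers of other marrow cells. They were tested with limma 3.58.1 camera at a preset correlation of 0.01 and a prior count of 2, on lists with at least 5 tested members, and again with a correlation estimated from the data. The groups, contrasts, lists, rule for named genes and the first set of alternatives were set before the data were examined.

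Alternatives were DESeq2 1.42.0 size factors, no low-count filter, the DESeq2 test, leaving out mitochondrially encoded genes, a replicate-number block, a term for library numbers from 17 up within the treated mice, only the 2 groups compared, translation efficiency without the mouse block, and leaving out each library or mouse. Added after the data were seen were fits without the RNA libraries of treated sgScramble replicate 4 and treated sgOgfod1 replicate 3, only mice with a footprint library, only protein-coding genes, limma voom with quality weights, and only genes passing the filter in both assays. The scripts were tested on simulated counts in which known genes were changed. For the treatment effect in sgScramble cells, a 2-fold change was called in 31.3% of simulated RNA genes, 71.6% of footprint genes and 2.99% of translation-efficiency genes, and a 4-fold change in 65.2%, 92.4% and 62.1%. Other comparisons of translation efficiency had less power. There a 4-fold change was called in 22.7% for treatment in sgOgfod1 cells, 25.8% and 34.8% for genotype under vehicle and treatment, and 3.03% for the interaction. A 1.5-fold shift of 1 list was called in every comparison, with 0 other lists called. Simulated genes were drawn independently of each other, so the 0 other lists do not carry over to real libraries. There, another split of the RNA libraries called 27 lists. RNA and footprints were simulated without a shared mouse effect, so the shares for translation efficiency may differ in paired libraries.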

Results

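The series profiled MLL-AF9 acute myeloid leukemia cells taken from the marrow of mice at the time of the largest response to chemotherapy. MLL-AF9 is a fusion of the histone methyltransferase gene Kmt2a with Mllt3 that drives myeloid leukemia. Cells carried either a scrambled guide RNA (sgScramble) or a guide against Ogfod1 (sgOgfod1). Ogfod1 is a prolyl hydroxylase that modifies the ribosomal protein uS12. Mice were either fed a diet with standard amino acids and given vehicle, or fed a diet without the branched-chain amino acids leucine, isoleucine and valine and given 5+3 chemotherapy. The latter consisted of cytarabine at 100 mg/kg for 5 days and doxorubicin at 3 mg/kg on the first 3 days. The design asks how treatment and loss of Ogfod1 alter mRNA levels and translated mRNAs. Diet and chemotherapy changed together, so their effects cannot be separated, and the combination is called treatment here. RNA was measured in 5 vehicle sgScramble, 5 vehicle sgOgfod1, 7 treated sgScramble and 6 treated sgOgfod1 mice. Ribosome footprints were measured in 3, 3, 4 and 2 of these mice in the same order.

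RNA totals for vehicle sgScramble replicates 1 to 5 were 31.9, 56.4, 49.2, 63.6 and 58.9 M counts (M for mega), and for vehicle sgOgfod1 replicates 1 to 5 they were 49.8, 56.1, 42.9, 37.7 and 46.9 M. Treated sgScramble replicates 1 to 7 held 56.1, 69.2, 79.6, 66.1, 71.8, 142.7 and 65.8 M, and treated sgOgfod1 replicates 1 to 6 held 55.3, 61.4, 52.9, 43.6, 61.4 and 53.1 M. Footprint totals were 9.5, 7.9 and 9.1 M for vehicle sgScramble replicates 2, 3 and 5, and 7.8, 5.7 and 14.6 M for vehicle sgOgfod1 replicates 3, 4 and 5. They were 9.5, 10.1, 7.6 and 7.9 M for treated sgScramble replicates 1, 2, 3 and 5, and 9.9 and 9.4 M for treated sgOgfod1 replicates 4 and 5. In a principal component analysis of RNA the first component held 31% of the variance. Treated sgScramble replicate 4, at 251.7, and treated sgOgfod1 replicate 3, at 140.4, stood apart from the other 21 libraries on it. Small nuclear RNAs took 6.91% ± 1.71 (SD, n = 4) of footprint counts in treated sgScramble mice and a mean of 2.10 to 2.54% in the other groups.

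Ogfod1 (ENSMUSG00000033009, chromosome 8, 94037198 to 94067921 on the plus strand, GRCm38, protein-coding) was lower in sgOgfod1 than in sgScramble cells in both assays. Its RNA level, in counts scaled to library size (CPM), was 22.7 ± 1.92 (SD, n = 5) in vehicle sgScramble, 10.8 ± 1.34 (n = 5) in vehicle sgOgfod1, 21.8 ± 6.22 (n = 7) in treated sgScramble and 9.20 ± 3.03 (n = 6) in treated sgOgfod1 mice. By replicate it was 24.9, 23.7, 19.7, 22.9 and 22.4 CPM in vehicle sgScramble and 11.5, 10.6, 11.7, 8.57 and 11.7 CPM in vehicle sgOgfod1 mice. It was 18.8, 22.2, 26.6, 12.3, 31.6, 22.7 and 18.4 CPM in treated sgScramble and 10.3, 13.0, 3.75, 9.15, 9.23 and 9.69 CPM in treated sgOgfod1 mice. The ranges met in 1 library, treated sgScramble replicate 4, whose 12.3 CPM lay below treated sgOgfod1 replicate 2. Footprints on Ogfod1 were 14.6 ± 0.872 CPM (n = 3), 2.42 ± 0.676 (n = 3), 15.0 ± 2.16 (n = 4) and 2.18 ± 1.04 (n = 2) in the same order, with no overlap between genotypes. Single mice had 13.7, 14.5 and 15.5, then 2.62, 2.98 and 1.67, then 14.4, 15.6, 12.4 and 17.5, and then 2.91 and 1.44 CPM. The footprint log2 fold change by genotype was -2.67 ± 0.24 (SE) under vehicle (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.68e-05; 3 of 3 libraries) and -2.77 ± 0.27 under treatment (adjusted p = 8.99e-05; 2 of 2). In RNA it was -1.25 ± 0.22 under treatment (adjusted p = 0.00608; 6 of 6). Under vehicle it was -1.07 ± 0.24, lower in 5 of 5 libraries but not past the threshold (adjusted p = 0.0846). Treatment gave log2 values of -0.06 ± 0.22 in sgScramble and -0.24 ± 0.23 in sgOgfod1 cells in RNA (adjusted p = 0.901 and 0.553).

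**Figure D1:**
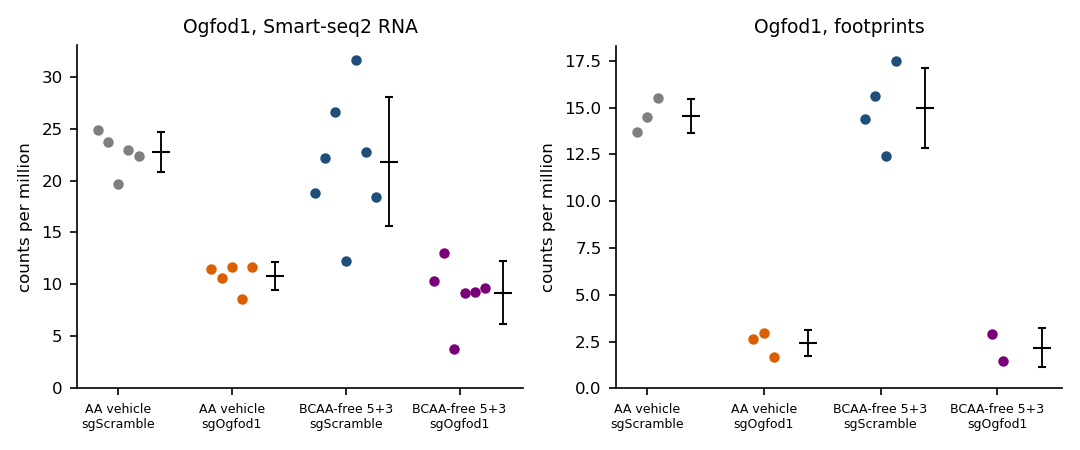
Ogfod1 in CPM per library in RNA (left) and ribosome footprints (right) for the 4 groups, each point 1 mouse, with bars for the mean and SD. Footprint means were 14.6 and 15.0 CPM in sgScramble groups and 2.42 and 2.18 CPM in sgOgfod1 groups.

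Treatment of sgScramble leukemia changed the level of many mRNAs. Of the named genes the monocyte-attracting chemokines Ccl8 and Ccl12 rose most, with log2 fold changes of 10.59 ± 1.73 (SE, adjusted p = 0.00035) and 9.77 ± 1.39 (adjusted p = 0.000113). Ccl8 went from 0.0545 ± 0.0522 CPM (SD, n = 5) to 96.0 ± 165 CPM (n = 7), and Ccl12 from 0.0106 ± 0.0157 to 11.3 ± 15.7 CPM. Vehicle levels reached 0 CPM for both, so the size and order of these fold changes are uncertain. The macrophage genes Vsig4, a complement receptor, Cd5l, a secreted scavenger protein, and Mrc1, the mannose receptor, rose by 9.29 ± 1.63, 6.99 ± 1.11 and 6.31 ± 0.86 (adjusted p = 0.000659, 0.000276 and 7.55e-05). So did the resistin-like gene Retnla, from 0.482 ± 0.402 to 57.1 ± 38.3 CPM, the neutrophil chemokine Cxcl2, from 0.287 ± 0.163 to 23.9 ± 16.8 CPM, and the protocadherin Pcdh11x, by 6.90 ± 1.16 (adjusted p = 3.64e-06, 5.79e-06 and 0.000474). Vehicle levels of Vsig4 and Pcdh11x reached 0 CPM too, so the size of their fold changes is also uncertain. The integrin Itga1, a collagen receptor subunit, fell from 341 ± 23.6 to 18.6 ± 17.5 CPM (log2 fold change -4.19 ± 0.78, adjusted p = 0.00109). The syntaxin-binding gene Stxbp6 fell from 15.9 ± 1.01 to 0.640 ± 0.427 CPM, the actin-severing gene Scin from 30.4 ± 6.24 to 3.00 ± 1.56 CPM, and Ms4a4c, of a family of tetraspan surface proteins, from 50.7 ± 6.22 to 6.54 ± 7.25 CPM (adjusted p = 0.000238, 0.000312 and 0.00524). The potassium channel Kcna3, the sphingosine phosphate receptor S1pr3 and the adaptor Apba1 fell by 3.93, 3.27 and 3.01 on the log2 scale (adjusted p = 0.00105, 0.00044 and 0.00829). Each of these genes moved the same way in 7 of 7 treated mice, which the rule for named genes fixed in advance for those that rose.

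Of 21474 genes tested in RNA, 2779 passed, 1846 higher and 933 lower in treated mice. Leaving out vehicle sgScramble replicate 4 gave 1834 genes. A term for library numbers from 17 up gave 1646. The share of higher genes, 66.4%, varied in fits chosen after the data were seen. Protein-coding genes alone gave 62.7%, voom with quality weights gave 5687 genes, 2871 higher and 2816 lower, only mice with a footprint library gave 1016 higher and 976 lower, and a fit without the pair of libraries standing apart gave 56.1%. The fold changes also followed coding length, with a rank correlation of -0.318 across 10974 genes, which are not independent replicates. In single libraries, against the mean of all RNA libraries, it ran from 0.176 to 0.427 in vehicle and from -0.404 to 0.321 in treated sgScramble mice. Whether this trend moves the gene lists below was not tested.

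Among the fixed lists, markers of tissue macrophages rose, with 15 of 16 tested members higher and 15 adjusted over the list alone, a median log2 fold change of 4.30, and an adjusted p of 5.77e-13 (0.204 with an estimated correlation). They included the receptor tyrosine kinase Axl at 5.08 ± 0.81 and the complement genes C1qa at 6.22 ± 1.01 and C1qb at 6.25 (adjusted p = 0.000276, 0.000323 and 0.000407). Their level varied between mice. Cd5l was 429, 152 and 153 CPM in treated sgScramble replicates 4, 6 and 7 and between 6.17 and 14.4 CPM in the other 4, and C1qb was 568, 196 and 210 CPM against 15.1 to 22.8 CPM. The footprint mice of this group are replicates 1, 2, 3 and 5. Neutrophil granule and granulocyte genes rose in 20 of 30 members (23 adjusted over the list alone, median 1.55, adjusted p = 1.46e-15; 0.11 with an estimated correlation), among them Wfdc21, Retnlg and Stfa2l1, the latter of a family that shares reads. NF-kB and inflammatory genes rose in 15 of 26 members (20 over the list alone, adjusted p = 5e-12; 0.204 with an estimated correlation), including the chemokine Ccl4 at 3.43 ± 0.50 and the signalling adaptor Traf1 (adjusted p for Ccl4 = 0.000143). Interferon-stimulated genes rose in 22 of 48 members (28 higher and 1 lower adjusted over the list alone, adjusted p = 6.11e-09; 0.391 with an estimated correlation), including Rtp4 at 4.35 ± 0.67 and Ifit3 at 4.25 ± 0.70, the latter uncertain because of its near copy Ifit3b.

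**Figure D2:**
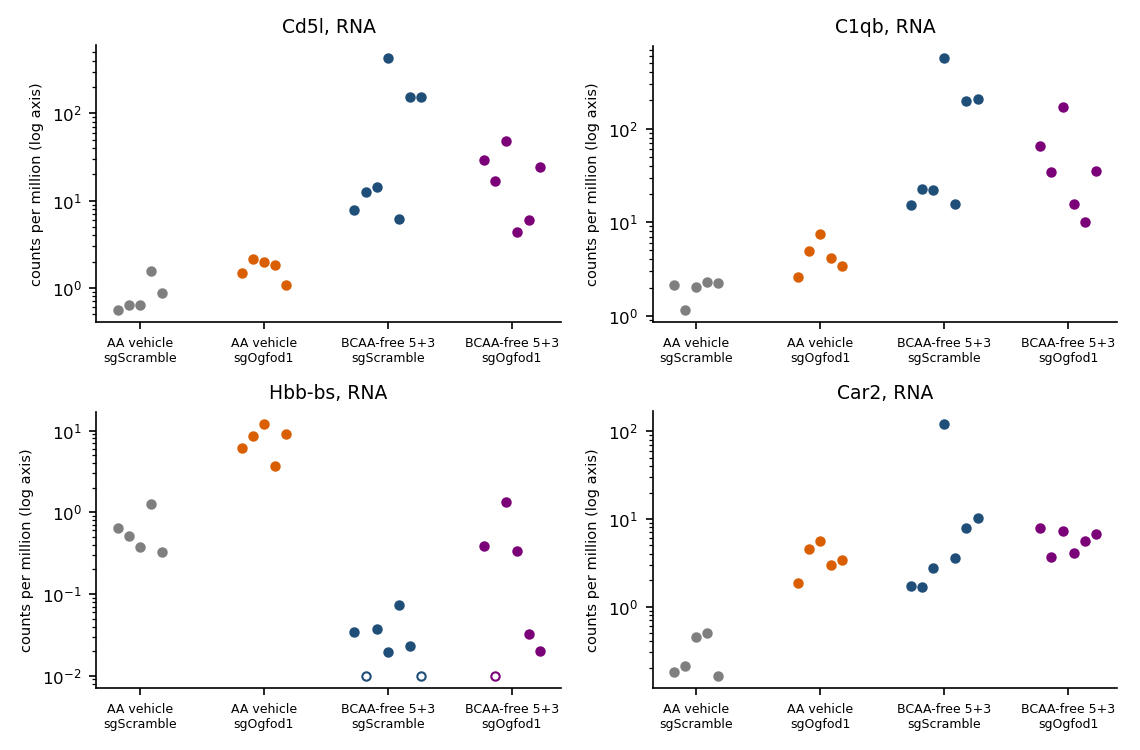
RNA level in CPM (log axis) of the macrophage genes Cd5l and C1qb and the erythroid genes Hbb-bs and Car2 in each library of the 4 groups, with open circles at the bottom for libraries with 0 counts. Cd5l reached 429, 152 and 153 CPM in 3 treated sgScramble mice and at most 14.4 CPM in the other 4.

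Targets of the tumour suppressor p53 rose in 21 of 38 members (24 adjusted over the list alone, median 0.90, adjusted p = 8.3e-12; 0.11 with an estimated correlation), among them the AKT inhibitor Phlda3 at 3.86 ± 0.52 and the stress kinase Plk2 (adjusted p for Phlda3 = 6.3e-05). Mitotic genes fell, with 28 of 51 lower (39 adjusted over the list alone, median -0.56, adjusted p = 2.62e-16; 0.294 with an estimated correlation), including the kinesin Kif23 (adjusted p = 5.59e-05) and the spindle checkpoint kinase Ttk at -0.80. Of 33 ATF4 and amino-acid response targets, 11 rose and 2 fell (11 and 2 adjusted over the list alone, adjusted p = 0.000918; 0.312 with an estimated correlation), with the cystine carrier Slc7a11 at 2.97 ± 0.40 and its partner Slc3a2 at 0.97 ± 0.13 among those that rose. Of 17 BCL2 family genes, 6 rose and 1 fell (adjusted p = 0.000802; 0.205 with an estimated correlation). The survival gene Bcl2 fell by 1.53 while the survival gene Bcl2l1 rose by 1.07 on the log2 scale (adjusted p = 0.000106 and 4.75e-05). In the MLL-AF9 and stemness list 1 member rose and 6 of 34 fell (adjusted p = 0.005; 0.432 with an estimated correlation), including the progenitor surface gene Cd93 at -1.78 ± 0.22 and the stem cell factor receptor Kit. Cholesterol synthesis genes fell in 9 of 25 members (11 over the list alone, adjusted p = 6.89e-05; 0.312 with an estimated correlation), among them Cyp51 and Sqle at -1.19 and -1.40.

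Further lists that passed at the preset correlation and lost their call with an estimated correlation, at adjusted p between 0.204 and 0.738, were these. Genes rose in 19 of 75 members of nuclear oxidative phosphorylation (adjusted p = 8.3e-12), 8 of 28 of translation initiation (2.39e-05), 7 of 17 of stromal and endothelial cells (6.22e-05), 4 of 80 of cytosolic ribosomal proteins (0.000191), 11 of 21 immediate early genes (0.000204), 5 of 46 of ribosome biogenesis (0.00861), 2 of 20 aminoacyl-tRNA synthetases (0.00966) and 4 of 19 T and NK cell genes (0.0117). Lists with members on both sides were megakaryocytes and platelets with 5 higher and 1 lower of 14 (0.00127), glycolysis with 7 and 1 of 20 (0.00948), and lysosome and autophagy with 7 and 2 of 30 (0.043, and 0.185 without the pair of libraries standing apart). DNA repair genes fell in 5 of 32 members (0.00122) and mitochondrially encoded proteins in 1 of 11 (0.00275). Adjusted over the list alone, 38 oxidative phosphorylation genes, 14 initiation factors and 7 synthetases passed, against 0 ribosomal proteins. With an estimated correlation 0 of the 36 lists passed. At the preset correlation 13 lists did not pass, namely B cells and plasma cells (adjusted p = 0.0927), antigen presentation (0.154), DNA replication and G1/S (0.486), monocyte and macrophage maturation (0.486), basophils and mast cells (0.512), translation elongation factors (0.519), erythroid cells (0.719), branched-chain amino acid catabolism (0.742), oxygenases acting on the translation machinery (0.742), the unfolded protein response (0.826), adhesion and niche genes (0.826), cytarabine and doxorubicin handling (0.874) and cytosolic heat shock genes (0.888). Single genes of these still passed, such as the cytarabine-phosphate hydrolase Samhd1, which rose by 1.87 ± 0.43, and Top2a, the target of doxorubicin, at -1.05 ± 0.24 (adjusted p = 0.00552 and 0.0059).

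Footprints in sgScramble cells moved in part with the mRNA. The ADP-ribosyl cyclase Cd38 rose from 0.405 ± 0.0912 (SD, n = 3) to 12.1 ± 4.60 CPM (n = 4), the matrix glycoprotein Thbs1 from 38.9 ± 6.92 to 841 ± 294 CPM, and Retnla and Mrc1 rose by 4.15 ± 0.33 and 3.80 ± 0.49 (SE, adjusted p = 3.18e-05, 0.000102, 9.21e-06 and 0.00127). The myeloid genes Ccl6, Retnlg and Wfdc21 rose by 3.62, 3.26 and 3.10 (adjusted p = 0.00123, 0.00648 and 2.88e-05). Footprints fell on Itga1, from 70.5 ± 5.01 to 3.22 ± 1.10 CPM, on Ms4a4c, from 12.0 ± 0.731 to 0.869 ± 0.428 CPM, on the monocyte-fate transcription factor Irf8, from 44.3 ± 3.66 to 4.27 ± 1.88 CPM, and on Ly86, a partner of a toll-like receptor, from 18.0 ± 0.865 to 3.17 ± 1.04 CPM (adjusted p = 0.00113, 4.88e-05, 0.00376 and 0.00391). The direction held in 4 of 4 treated mice for each. Of 18290 genes tested, 2847 passed, 1486 higher and 1361 lower, of which 847 were pseudogenes. Among the protein-coding genes of this fit 715 were higher and 1178 lower, while a fit of protein-coding genes alone, chosen after the data were seen, gave 1137 higher and 949 lower. Leaving out vehicle sgScramble replicates 2, 3 or 5 gave 1426, 1365 and 1842 genes, and a term for library numbers gave 1503.

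Ribosomal protein genes gained footprints in 36 of 80 members (52 adjusted over the list alone, median 0.30, adjusted p = 1.41e-14; 0.506 with an estimated correlation), including Rpl35 at 0.70 and Rpl17 at 0.58. Reads shared with pseudogenes make these values uncertain. Translation initiation factors rose in 10 of 28 and elongation factors in 5 of 22 members (15 and 11 over the list alone, adjusted p = 2.37e-05 and 0.000174; 0.444 and 0.448 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 24 members (20 over the list alone, median -0.64, adjusted p = 4.96e-10; 0.333 with an estimated correlation), including the farnesyl diphosphate synthase Fdps at -0.93 ± 0.11 and the regulator Srebf2 at -1.01 ± 0.12 (adjusted p = 8.45e-05 and 0.000143). Mitotic genes fell in 23 of 51 members (adjusted p = 4.96e-10; 0.506 with an estimated correlation). Footprints on macrophage markers rose in 10 of 14 members, on neutrophil genes in 15 of 30 with 1 lower, and on p53 targets in 13 of 33 with 1 lower (adjusted p = 1.12e-10, 2.33e-08 and 5.18e-07; 0.333, 0.448 and 0.333 with an estimated correlation). The drug efflux pump Abcb1b, from the drug-handling list that did not pass (adjusted p = 0.97), fell by 3.10 on the log2 scale (adjusted p = 4.1e-05). In all, 12 lists passed at the preset correlation and 0 with an estimated one.

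Translation efficiency in sgScramble cells was higher after treatment for 120 of 28606 genes and lower for 146. Named genes with more footprints per mRNA were the cytokine receptor Il31ra at 1.84 ± 0.32 (SE), the sorting nexin Snx30 at 1.72 ± 0.21, the scaffold Ahnak at 2.31 ± 0.37, the spectrin Sptbn1 at 1.58 ± 0.23 and the cytoskeletal linker Macf1 at 1.26 ± 0.15 (adjusted p = 0.0292, 0.000937, 0.0247, 0.00719 and 0.000792; 4 of 4 mice each). Mean Ahnak footprints went only from 39.2 to 41.9 CPM. Sptbn1 and Macf1 have 2363 and 7355 codons. The longest of 10 length classes had a median efficiency change of 0.11, against -0.02 in the shortest, and a median RNA change of -0.28. What coding length adds to these values was not tested. Named genes with fewer were the stem cell factor gene Kitl at -3.82 ± 0.44, the neutrophil antigen Ly6g at -1.64 ± 0.29 and the smooth muscle actin Acta2 at -1.69 ± 0.22 (adjusted p = 0.00195, 0.0218 and 0.0028). The size of the Kitl value is uncertain, since it rests on 3 to 14 RNA counts in each vehicle mouse. H2-Q10 and Hist1h2bj, at -3.07 and -1.72, share reads with close family members and are uncertain. With DESeq2 size factors the share of higher genes among those called went from 45.1% to 60.1%, so the balance of directions rests on the scaling. Without the mouse block 56 genes passed over the matched mice and 13 over all libraries, against 1077 with the DESeq2 test and 817 with no low-count filter. Leaving out 1 mouse gave 77, 49 or 91 genes without vehicle replicates 2, 3 or 5, and 140 or 83 without treated replicates 1 or 2. Immediate early genes had lower efficiency (1 of 22 called and 7 adjusted over the list alone, median -0.52, adjusted p = 3.55e-06; 0.0721 with an estimated correlation), with the AP-1 component Jund at -1.34 ± 0.24 (adjusted p = 0.0131). Mitochondrially encoded proteins had a median of 0.72 (0 of 13 called and 7 over the list alone, adjusted p = 5.43e-05; 0.699 with an estimated correlation).

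**Figure D3:**
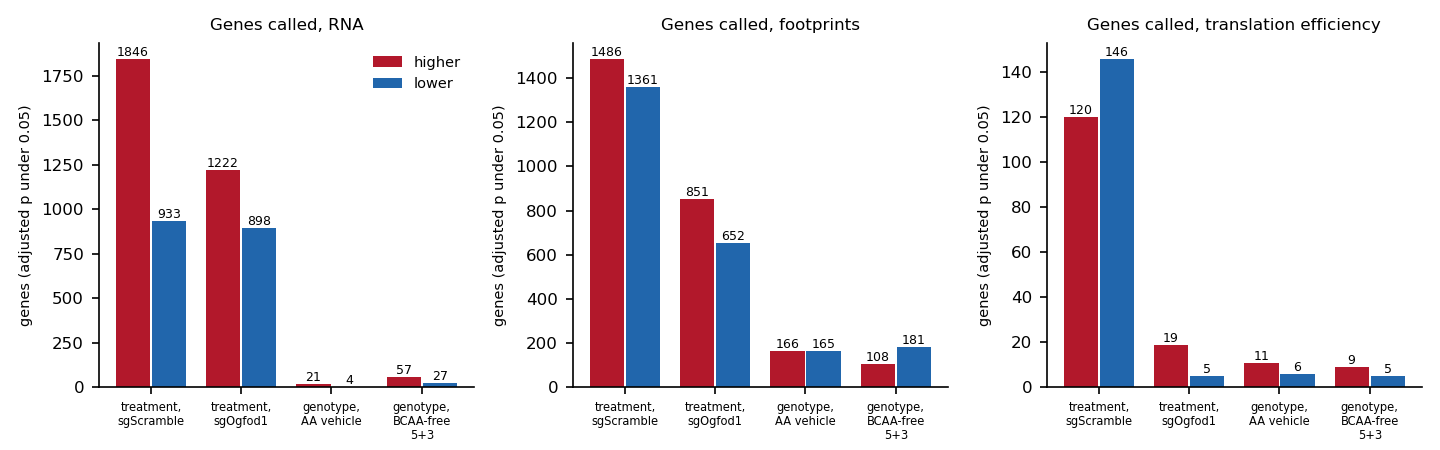
Number of genes with an edgeR adjusted p under 0.05 in RNA, ribosome footprints and translation efficiency, for the treatment effect in each genotype and the genotype effect in each treatment. Bars stand side by side, with higher genes on the left and lower genes on the right of each pair. Treatment moved 2779 and 2120 genes in RNA against 25 and 84 for genotype.

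In sgOgfod1 leukemia, treatment raised several of the same genes in RNA. Pcdh11x rose by 8.43 ± 1.32 (SE), Retnla from 0.433 to 14.5 ± 7.04 CPM (SD, n = 6), Ccl8 by 4.91 ± 1.27 and Cxcl2 by 4.60 ± 0.61 (adjusted p = 0.000314, 5.57e-05, 0.0155 and 7.51e-05). The size of the Pcdh11x value is uncertain, since vehicle levels reached 0 CPM and treated mice ran from 0.261 to 50.7 CPM. The endothelial lipase Lipg rose from 0.764 to 21.3 ± 22.0 CPM and Cd38 from 7.02 ± 4.32 to 138 ± 44.7 CPM (adjusted p = 0.00478 and 2.4e-05). The cytochrome Cyp2a5 rose by 4.88 (adjusted p = 0.00037), a value that reads of Cyp2a4 make uncertain. The matrix gene Fn1 fell from 198 ± 116 (n = 5) to 7.05 ± 11.2 CPM, Scin from 34.7 ± 35.6 to 1.40 CPM, Stxbp6 from 10.0 ± 5.92 to 0.253 CPM, the eosinophil peroxidase Epx from 12.6 ± 14.4 to 0.353 CPM, and Ms4a4c from 52.5 ± 26.1 to 2.36 ± 3.30 CPM (adjusted p = 0.00234, 7.14e-05, 0.000245, 0.00223 and 0.000669). Each held in 6 of 6 treated mice. Of 21474 genes, 1222 rose and 898 fell, 2120 in all, and the fold changes followed coding length with a rank correlation of -0.406. Other splits of these libraries gave trends as large, such as 0.473, so the value alone does not tie the trend to treatment. Leaving out vehicle sgOgfod1 replicates 2 or 4 gave 1344 and 1393 genes. In fits chosen after the data were seen, only mice with a footprint library gave 850, with the balance turned to 382 higher and 468 lower, voom with quality weights gave 1874 higher and 1817 lower, and a fit without the pair of libraries standing apart gave 3877.

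Neutrophil genes rose in 20 of 30 members (24 adjusted over the list alone, median 1.64, adjusted p = 7.85e-18), a call that held with an estimated correlation (adjusted p = 0.0365). Erythroid genes fell in 6 of 18 members (median -2.07, adjusted p = 6.04e-07), a call that also held (adjusted p = 0.0299 with an estimated correlation). Among them Hbb-bs was at -4.51 ± 0.83 and the band 3 anion exchanger Slc4a1 at -5.11 ± 1.40 (adjusted p = 0.00125 and 0.022), the globin with reads that its near copies can share. Vehicle sgOgfod1 mice were the group with the highest Hbb-bs, at 3.65 to 12.0 CPM. This did not hold for the erythroid gene Car2, with 121 CPM in treated sgScramble replicate 4 and 1.66 to 10.3 CPM in the rest of that group. Targets of p53 rose in 19 of 38, macrophage markers in 11 of 16, NF-kB genes in 9 of 26 and ATF4 targets in 8 of 33 members (adjusted p = 2.73e-10, 6.04e-07, 2.53e-06 and 4.69e-05; 0.102, 0.418, 0.418 and 0.379 with an estimated correlation), including the pseudokinase Trib3 at 4.41 and Slc7a11 at 3.46. Of the MLL-AF9 and stemness list 9 of 34 fell (adjusted p = 0.00509; 0.522 with an estimated correlation), such as Cd34 at -2.55, a surface marker of progenitors. Of 51 mitotic genes 1 fell and 0 passed adjusted over the list alone (median -0.23, adjusted p = 0.00105; 0.734 with an estimated correlation). Of 48 interferon-stimulated genes 1 rose and 2 fell (adjusted p = 0.846). In all, 19 lists passed at the preset correlation and 2 with an estimated one.

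**Figure D4:**
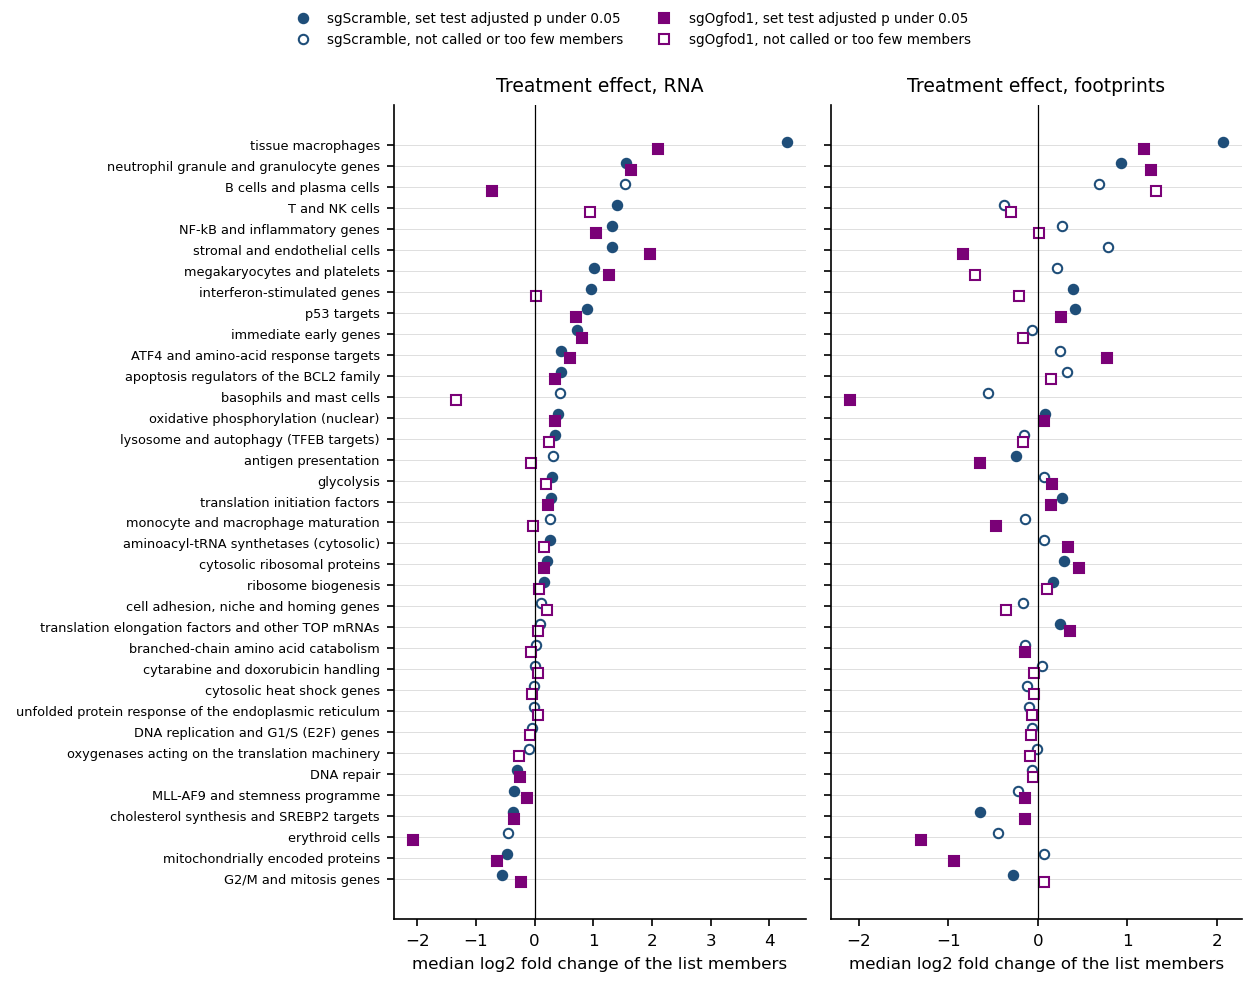
Median log2 fold change by treatment of each fixed gene list in RNA and in ribosome footprints, with circles for sgScramble and squares for sgOgfod1 cells and filled symbols where the list test passed at the preset correlation. Macrophage markers had RNA medians of 4.30 and 2.11, and mitotic genes of -0.56 and -0.23.

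Footprints of treated sgOgfod1 cells rest on 2 mice. Lipg rose from 0.439 ± 0.238 (SD, n = 3) to 38.3 ± 11.1 CPM (n = 2), the serine/threonine kinase Pim1 from 7.17 ± 4.93 to 102 ± 60.6 CPM, Wfdc21 to 14.3 ± 0.375 CPM and Cd38 to 12.4 ± 1.74 CPM (adjusted p = 0.0099, 0.0123, 3.15e-05 and 0.000324). Fn1 fell from 64.9 ± 24.1 to 1.82 ± 0.54 CPM, Cd34 from 38 ± 9.34 to 2.05 ± 1.91 CPM and Irf8 from 32.3 ± 19.4 to 1.92 ± 0.826 CPM (adjusted p = 0.00448, 0.00248 and 0.0125). Ms4a4c had 10.1 ± 4.29 CPM under vehicle and 0 counts in both treated mice, so it was at least 33-fold lower against a floor of 3 counts per library (adjusted p = 0.000117). All of these held in 2 of 2 treated mice. Of 18290 genes 851 rose and 652 fell, 560 of them pseudogenes, and among protein-coding genes 307 rose and 576 fell, while a fit of protein-coding genes alone, chosen after the data were seen, gave 497 higher and 444 lower. Both mice have library numbers from 17 up, and with a term for those numbers 6 genes passed in place of 1503. Without vehicle replicate 3 or treated replicate 5 the count was 848 and 949. A fit of only these 2 groups gave 206, and voom with quality weights, added after the data were seen, gave 782.

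Ribosomal protein genes, uncertain because of reads that pseudogenes may share, gained footprints in 49 of 80 members (71 adjusted over the list alone, median 0.47, adjusted p = 8.35e-27; 0.41 with an estimated correlation). Antigen presentation genes lost them in 14 of 19 (median -0.65, adjusted p = 1.32e-08; 0.41), including the peptide transporter Tap2 at -0.65 ± 0.13 and H2-K1, of a family that shares reads. Mitochondrially encoded proteins fell in 4 of 13 (13 over the list alone, median -0.93, adjusted p = 9.69e-08; 0.433), with mt-Cytb at -1.16 ± 0.25. Aminoacyl-tRNA synthetases rose in 6 of 20 (10 over the list alone, adjusted p = 5.68e-05; 0.442), including Cars at 0.85 and Nars at 0.63. ATF4 targets rose in 6 of 29 (adjusted p = 1.71e-06; 0.41), and monocyte maturation genes rose in 2 and fell in 14 of 31 (adjusted p = 5.7e-05; 0.442). The last value in each of these brackets is the adjusted p with an estimated correlation, and 0 of the 19 lists that passed at the preset correlation held with it.

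Translation efficiency in sgOgfod1 cells passed for 24 genes, 19 higher and 5 lower after treatment. Il31ra at 3.71 ± 0.43 (SE), Snx30 at 1.97 ± 0.25, the pore-forming macrophage protein Mpeg1 at 1.42 ± 0.17 and the dynein heavy chain Dync1h1 at 1.17 ± 0.19 were higher, and Kitl at -4.08 ± 0.50, again on few RNA counts, was lower (adjusted p = 0.0138, 0.00316, 0.00275, 0.014 and 0.00582; 2 of 2 mice each). Mean Mpeg1 footprints themselves fell from 144 to 12.3 CPM, so its ratio to mRNA rose while its footprints fell. Dync1h1 encodes a very long protein, and the longest of 10 length classes had a median efficiency change of 0.21, against 0.07 in the shortest. Eef1a1, Rpl10 and Tubb2a, at 1.07, 1.02 and 1.41, have processed pseudogenes or close paralogs and are uncertain. All 80 ribosomal proteins had a positive value (1 called and 27 adjusted over the list alone, median 0.56, adjusted p = 8.25e-19; 0.708 with an estimated correlation). Reads shared with pseudogenes make this list uncertain too. With DESeq2 size factors 12 genes passed, and the share of higher genes went from 79.2% to 66.7%. Without the mouse block 7 and 5 genes passed over matched mice and all libraries, against 75 with the DESeq2 test and 276 with no low-count filter. Without vehicle replicates 3, 4 or 5 there were 10, 15 and 14 genes, and without treated replicate 4 there were 11.

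The treatment effects in the 2 genotypes come from separate libraries, but from 1 fit with a shared estimate of the spread. In both genotypes vehicle libraries have numbers up to 10 and treated libraries from 11 up. Agreement between genotypes therefore does not set treatment apart from library order. In RNA 857 genes rose in both, against 105 for independent lists, 388 fell in both, against 39.0, and 0 went in opposite directions. The correlation of log2 fold changes across 21474 genes was 0.62. In footprints 440 rose in both and 351 fell in both, against 69.1 and 48.5, with 0 opposite and a correlation of 0.532. Across 13565 genes the RNA and footprint fold changes of treatment correlated at 0.586 in sgScramble and 0.501 in sgOgfod1 cells, and those of genotype at 0.425 under vehicle and 0.372 under treatment. In sgScramble cells 414 genes rose and 335 fell in both assays, and 9 went in opposite directions. Genes are not independent replicates.

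Under vehicle, 25 mRNAs differed by genotype at the threshold. The insulin receptor adaptor Grb14 rose from 0.532 ± 0.195 to 10.7 ± 1.32 CPM (SD, n = 5 each) and Ndrg2, of the N-myc downstream-regulated family, from 0.868 ± 0.409 to 10.7 ± 3.22 CPM, with log2 fold changes of 4.32 ± 0.83 (SE) and 3.62 ± 0.50 (adjusted p = 0.0386 and 0.00253; 5 of 5 libraries each). The basophil protease Mcpt8 rose from 5.36 ± 0.554 to 30.3 ± 38.3 CPM, with 98.5 CPM in replicate 4 and 10.1 to 18.6 CPM in the other 4 (adjusted p = 0.0386). The collagen chain Col4a1 fell from 30.3 ± 6.14 to 7.01 ± 2.70 CPM and the microtubule gene Eml5 from 191 ± 25.7 to 74.5 ± 29.6 CPM, while the ferritin receptor Ncoa4 was at -0.59 ± 0.10 (adjusted p = 0.0478, 0.0478 and 0.0092; 5 of 5 each). Of 21474 genes 21 rose and 4 fell. Leaving out sgScramble replicates 1 to 5 in turn gave 6, 7, 11, 9 and 3 genes, and leaving out sgOgfod1 replicates 1 to 4 gave 15, 10, 12 and 10. The DESeq2 test gave 115, a fit of only these 2 groups 497, of which 314 were higher and 183 lower, and no low-count filter 16. Voom with quality weights, chosen after the data were seen, gave 221 higher and 205 lower.

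Markers of erythroid cells were higher in vehicle sgOgfod1 mice, with 16 of 18 members positive, 0 called over all genes and 8 adjusted over the list alone, a median of 2.57 and an adjusted p of 1.82e-20 (3.11e-05 with an estimated correlation). Hbb-bs stood at 3.65 to 12.0 CPM against 0.324 to 1.26 CPM in vehicle sgScramble mice, and the carbonic anhydrase Car2 at 1.85 to 5.53 against 0.162 to 0.498 CPM, with no overlap between the groups (adjusted p = 0.11 and 0.295 over all genes). Protocols include a lysis of red blood cells and a sort for GFP. B cell and plasma cell markers were positive in 18 of 20 members with 0 called in either way of adjusting (median 0.97, adjusted p = 5.51e-10; 0.0269 with an estimated correlation). Interferon-stimulated genes were positive in 44 of 48 members, with 0 called and 3 adjusted over the list alone (median 0.44, adjusted p = 6.24e-10; 0.931 with an estimated correlation). Of 12 lists that passed at the preset correlation, the erythroid and B cell lists held.

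By genotype under vehicle more genes passed in footprints than in RNA, 331 against 25. The assays differ in power, since simulated 2-fold changes in this comparison were called in 65.7% of footprint and 32.8% of RNA genes. The gap was much smaller in a fit of only these 2 groups, whose counts are given in the section on processing. The mannose 6-phosphate receptor Igf2r rose from 10.7 ± 2.55 to 49.2 ± 2.90 CPM (SD, n = 3 each), Ahnak from 39.2 ± 4.13 to 132 ± 31.5 CPM, Sptbn1 from 25.3 ± 1.02 to 80.0 ± 38.4 CPM, and the interferon-inducible Slfn5 by 2.14 ± 0.31 (SE, adjusted p = 0.0389, 0.000554, 0.0202 and 0.00396). The chromatin protein and alarmin gene Hmgb1 rose from 95.2 ± 11.5 to 219 ± 30.7 CPM (adjusted p = 0.000513), a value that many pseudogenes with its sequence make uncertain. The laminin chain Lamb3 fell from 23.9 ± 6.81 to 3.38 ± 1.20 CPM, the immediate early transcription factor Egr1 from 13.3 ± 4.73 to 2.38 ± 1.21 CPM and the platelet integrin Itgb3 from 12.9 ± 0.951 to 5.2 ± 1.84 CPM (adjusted p = 0.00118, 0.00159 and 0.0155). All held in 3 of 3 sgOgfod1 mice. Of 18290 genes 166 rose and 165 fell, 141 of them pseudogenes. Footprint fold changes followed coding length, with a rank correlation of 0.275 across 10974 genes. Another split of these libraries gave 0.278, so the value alone does not tie the trend to genotype. In a separate fit of 10974 protein-coding genes with a known coding length, of 133 genes that rose, 28.6% had more than 1591 codons, against 1.61% of 124 that fell. After the length trend of each library was removed from that fit, 62 rose and 86 fell. Leaving out sgScramble replicates 2, 3 or 5 gave 111, 70 and 80 genes, and leaving out sgOgfod1 replicates 3 or 4 gave 103 and 148, against 1012 with no low-count filter.

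Interferon-stimulated genes rose in 6 of 42 members in footprints (14 adjusted over the list alone, median 0.35, adjusted p = 1.36e-07), including Ifi204 at 1.59 ± 0.31 and Ifit3 at 3.38 ± 0.64, the latter uncertain (adjusted p = 0.018 and 0.013). Translation initiation factors rose in 4 of 28 members, among them the eIF3 subunit Eif3a at 0.54 ± 0.10 and Eif4g1 at 0.52, and the DNA repair list in 3 of 32, among them the kinase Atr at 0.84 ± 0.14 (adjusted p = 0.0021 for both lists). Lysosome genes fell in 3 of 30, including the tetraspanin Cd63 at -0.43 (adjusted p = 0.00129). With an estimated correlation these 4 lists had adjusted p = 0.657, and 0 of the 17 lists held. No list was tested again after the length trend above was removed, so what that trend adds to these lists is not known.

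Translation efficiency by genotype under vehicle passed for 17 genes, 11 higher and 6 lower in sgOgfod1 cells. Those higher included genes of very long cytoskeletal proteins, Sptbn1 at 1.55 ± 0.24 (SE), the nuclear envelope protein Syne2 at 1.53 ± 0.23, the plectin Plec at 1.27 ± 0.20, the utrophin Utrn at 1.22 ± 0.20 and Macf1 at 1.15 ± 0.16, as well as Fn1 at 1.18 ± 0.17 (adjusted p = 0.0334, 0.0151, 0.0267, 0.0201, 0.0113 and 0.0118; 3 of 3 mice each). Ogfod1 was lower at -1.67 ± 0.30 (adjusted p = 0.0367), a call lost with DESeq2 size factors (adjusted p = 0.0514) and without sgScramble replicates 2, 3 or 5 or sgOgfod1 replicates 3 or 5 (adjusted p = 0.0509, 0.13, 0.182, 0.257 and 0.119). Lamb3 was lower at -2.64 ± 0.39 and the haemoglobin genes Hbb-bs and Hba-a1 at -3.74 ± 0.57 and -3.03 ± 0.43, the globins uncertain because of their near copies (adjusted p = 0.0311, 0.0336 and 0.0118). The size of the globin values is uncertain too, since Hbb-bs had 20 to 29 and Hba-a1 3 to 13 RNA counts in the vehicle sgScramble mice, and the mean log2 ratio of footprints to RNA per mouse went only from 4.69 to 3.48 for Hba-a1 and from 3.75 to 1.15 for Hbb-bs. The correlation of coding length with the efficiency change was 0.304 across 10974 genes. The median change rose from -0.19 in the shortest to 0.17 in the longest of 10 length classes. Without the mouse block 1 gene passed over the matched mice and 2 over all libraries, against 174 with the DESeq2 test, 401 with no low-count filter, and 131 with protein-coding genes alone, of which 63 were higher and 68 lower. Without sgScramble replicates 3 or 5 there were 9 and 4 genes, without sgOgfod1 replicate 3 there were 7, and without sgOgfod1 replicate 5 there were 26.

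**Figure D5:**
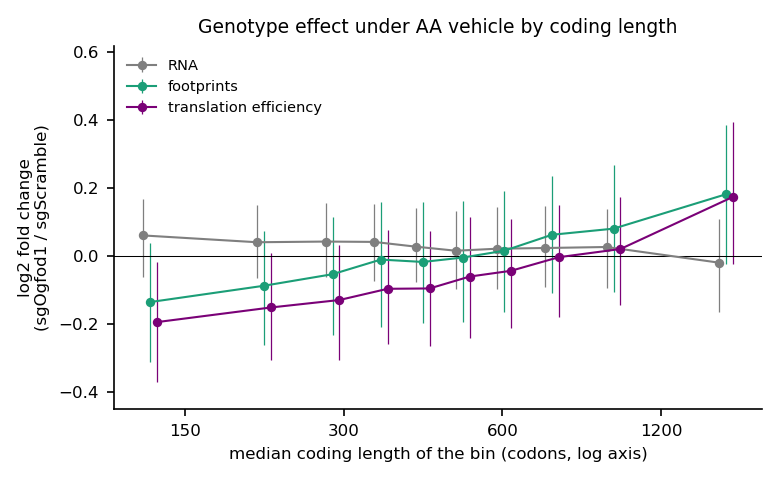
Median log2 fold change by genotype under vehicle (points) with the 25th to 75th percentile (bars) in 10 classes of coding length, in codons, for RNA, ribosome footprints and translation efficiency. In translation efficiency the median went from -0.19 at 129 codons to 0.17 at 1591 codons.

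Under treatment, 84 mRNAs differed by genotype at the threshold. The homeobox gene Hoxa11 rose from 1.05 ± 0.35 (SD, n = 7) to 16.5 ± 12.7 CPM (n = 6) and the cell cycle inhibitor Cdkn1c from 10.2 ± 4.07 to 60.3 ± 29.0 CPM, by 3.99 ± 0.54 (SE) and 2.56 ± 0.29 on the log2 scale (adjusted p = 0.000531 and 6.23e-05). The zinc finger gene Sp9 and the peroxisomal oxidase Acox2 rose by 5.10 and 3.75 (adjusted p = 0.000767 and 0.0037). The calcium release channel Ryr2 fell from 13.5 ± 5.98 to 0.864 ± 0.472 CPM, the macrophage receptor Adgre1 from 384 ± 159 to 162 ± 69.2 CPM, the death-associated kinase Dapk1 from 11.6 ± 1.83 to 4.84 ± 1.68 CPM and the retinoid receptor Rxra by 1.01 on the log2 scale (adjusted p = 2.39e-05, 0.0166, 0.0031 and 0.00897). Each held in 6 of 6 sgOgfod1 mice. Of 21474 genes 57 rose and 27 fell, 84 in all. Without the pair of libraries standing apart, a choice made after the data were seen, 394 passed. Leaving out sgScramble replicate 4 gave 376, and sgOgfod1 replicates 1, 3, 4 or 5 gave 307, 149, 48 and 140. DESeq2 gave 575, and a fit of only these 2 groups 13. The share of higher genes, 67.9%, was 53.9% with DESeq2, and only mice with a footprint library gave 278 higher and 309 lower. In 8 genes RNA rose and in 2 it fell with loss of Ogfod1 both under vehicle and under treatment, against 0.1 and 0 for independent lists.

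As a group, mitotic genes had higher RNA in treated sgOgfod1 mice, with 49 of 51 positive, 0 called and 15 adjusted over the list alone (median 0.33, adjusted p = 1.79e-14; 0.978 with an estimated correlation). Macrophage markers were negative in all 16 members with 0 called (median -1.22, adjusted p = 0.0356; 0.978 with an estimated correlation), and interferon-stimulated genes were positive in 2 of 48 with 0 called (median -0.50, adjusted p = 2.38e-05; 0.978). The last value is again with an estimated correlation, with which 0 of the 7 lists that passed held. Without the pair of libraries standing apart the macrophage and interferon lists lost their call at the preset correlation too (adjusted p = 0.127 and 0.15).

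Footprints under treatment compared 2 sgOgfod1 with 4 sgScramble mice. Cdkn1c rose from 3.61 ± 0.476 to 21.4 ± 15.3 CPM and Igf2r from 20.2 ± 3.54 to 85.3 ± 66.4 CPM, with the homeobox gene Hoxa10 at 0.97 ± 0.19 (SE, adjusted p = 0.0176, 0.041 and 0.0176). Cd34 fell from 13.8 ± 4.80 to 2.05 ± 1.91 CPM, the calcium-binding gene S100a6 from 234 ± 71.1 to 38.3 ± 6.55 CPM, Thbs1 from 841 ± 294 to 200 ± 44.9 CPM and the protease inhibitor Slpi by 1.96 ± 0.18 on the log2 scale (adjusted p = 0.0319, 0.0127, 0.0198 and 8.99e-05). The direction held in 2 of 2 sgOgfod1 mice. Of 18290 genes 108 rose and 181 fell, 63 of them pseudogenes. A term for library numbers from 17 up, which both sgOgfod1 mice have, gave 2 in place of 289. Without sgScramble replicates 2, 3 or 5 the count was 140, 116 and 438, and without sgOgfod1 replicate 4 or 5 it was 135 and 505. A fit of only these 2 groups gave 94, and voom with quality weights, chosen after the data were seen, 52.

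Mitotic genes gained footprints in 19 of 51 members (42 adjusted over the list alone; all 51 positive, median 0.48, adjusted p = 2.64e-27; 0.286 with an estimated correlation), among them the motility receptor gene Hmmr at 0.86 ± 0.11 and the kinase Plk1 at 0.69. Aminoacyl-tRNA synthetases rose in 2 of 20 members (12 over the list alone, median 0.43, adjusted p = 2.32e-08; 0.286), Cars and Iars at 0.84 and 0.62. Monocyte maturation genes fell in 2 of 31 (10 over the list alone, adjusted p = 3.49e-08; 0.286), p53 targets were negative in all but 6 of 33 members with 0 called and 10 lower over the list alone (adjusted p = 2.46e-06; 0.286), and mitochondrially encoded proteins were positive in 0 of 13 with 0 called and 6 lower over the list alone (adjusted p = 8.47e-07; 0.333). The last value is with an estimated correlation, which ended the call of all 22 lists. Translation efficiency passed for 14 genes, 9 higher and 5 lower, with Dync1h1 at 1.39 ± 0.18 (SE), Mpeg1 at 1.19 ± 0.17 and the ubiquitin ligase Ubr4 at 0.99 ± 0.16 higher and Mettl26 at -1.29 ± 0.21 lower (adjusted p = 0.00664, 0.00717, 0.0184 and 0.0247; 2 of 2 mice each). Mean Mpeg1 footprints were lower in treated sgOgfod1 than in treated sgScramble mice, at 12.3 against 27.5 CPM. The efficiency change followed coding length here too, with a rank correlation of 0.299 and a median from -0.10 in the shortest to 0.30 in the longest of 10 classes, and Dync1h1 and Ubr4 encode very long proteins. Ogfod1 was not called here, with log2 values from -1.98 to -0.89 when 1 mouse was left out. Without the mouse block 7 genes passed over the matched mice and 0 over all libraries, against 162 with the DESeq2 test, 341 with no low-count filter and 1932 at an unadjusted p under 0.05. Without sgScramble replicates 3 or 5 there were 22 and 42 genes, and without sgOgfod1 replicates 4 or 5 there were 8 and 30.

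The test of whether treatment acted differently in the 2 genotypes called 0 of 21474 genes in RNA with edgeR, against 975 at an unadjusted p under 0.05 and 18 with DESeq2, and 0 of 28606 in translation efficiency, against 1663 and 65. Of simulated 4-fold changes, this test called 51.5% in RNA and 3.03% in translation efficiency, so the 0 in translation efficiency excludes little. In footprints it called 12 of 18290 genes. Ahnak had an interaction of -3.27 ± 0.30 (SE, adjusted p = 0.000734), with 39.2, 132, 41.9 and 14.6 CPM in vehicle sgScramble, vehicle sgOgfod1, treated sgScramble and treated sgOgfod1 mice. The transglutaminase Tgm1 was at 1.20 ± 0.19 and Hmgb1 at -1.26 ± 0.21 (adjusted p = 0.0221 and 0.0328), and the other 9 were pseudogenes. A term for library numbers from 17 up gave 1 gene, and protein-coding genes alone gave 3. Without vehicle sgScramble replicate 2 or 5, vehicle sgOgfod1 replicate 3 or treated sgScramble replicate 3 there was 1 gene, and without vehicle sgOgfod1 replicate 4, treated sgScramble replicate 5 or treated sgOgfod1 replicate 5 there were 46, 23 and 93. Without vehicle sgOgfod1 replicate 4, treated sgScramble replicate 1 or treated sgOgfod1 replicate 5, translation efficiency had 1, 2 and 3 genes. Among lists the erythroid genes differed in RNA (median -1.96; 0 of 18 called and 2 lower adjusted over the list alone, adjusted p = 5.79e-13; 8e-04 with an estimated correlation). The interferon list had a median of -0.91 (0 of 48 called and 14 lower over the list alone, adjusted p = 4.71e-18; 0.397 with an estimated correlation), and mitotic genes 0.31 in RNA and 0.38 in footprints (0 called in each, adjusted p = 2.26e-13 and 6.54e-18; 0.618 and 0.486 with an estimated correlation). Mitochondrially encoded proteins had -1.06 in footprints (0 called and 13 lower over the list alone, adjusted p = 2.27e-09; 0.494 with an estimated correlation).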

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

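The tests of the Hmgb1 mRNA and of sequence shared with its pseudogenes were chosen after the result was seen. For 47 genes and 7 library measures, 270 groups of 4 to 7 libraries were searched for a library far from the others of its group, by the gap to the nearest library over the whole range of the group, on the log scale for genes. Of these, 26 stood out, and chance alone makes about 1 in 20 groups stand out.

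Most of these libraries were RNA libraries. In vehicle sgScramble mice they were replicate 3 for Pcdh11x (0.482 CPM, others 0 to 0.105), replicate 5 for Egr1 (75.4, others 24.4 to 29.8) and replicate 2 for C1qb (1.16, others 2.05 to 2.30). In vehicle sgOgfod1 mice they were replicate 2 for Pcdh11x (0.149, others 0 to 0.0243), replicate 1 for Dapk1 (3.14, others 4.41 to 5.01), replicate 5 for Sptbn1 (326, others 356 to 361), and replicate 4 for Apba1 (4.46, others 15.8 to 24.3), Mcpt8 (98.5, others 10.1 to 18.6), Col4a1 (2.26, others 7.38 to 8.64) and Thbs1 (31.7, others 48.9 to 56.7). In treated sgScramble mice, replicate 6 had 142.7 M counts (others 56.1 to 79.6) and an Egr1 level of 56 CPM (others 21.8 to 32.4). Replicate 4 of that group had a mitochondrial share of 0.23% (Wilson 95% interval 0.226 to 0.2283%, others 0.58 to 0.83%), and its levels of Col4a1 (2.62 CPM, others 7.02 to 13.3), Thbs1 (212, others 760 to 1480), Igf2r (0.466, others 11.7 to 16.9), Sptbn1 (4.21, others 197 to 340) and Car2 (121, others 1.66 to 10.3) stood apart too. In treated sgOgfod1 mice they were replicate 3 for Ogfod1 (3.75 CPM, others 9.15 to 13.0) and Sptbn1 (75.1, others 189 to 323), replicate 1 for Ms4a4c (9.05, others 0.504 to 1.49) and replicate 2 for Col4a1 (23.1, others 4.78 to 7.68). Among footprints of treated sgScramble mice they were replicate 3 for Stxbp6 (0.294 CPM, others 0.109 to 0.136), replicate 2 for Fn1 (19.4, others 6.04 to 6.75) and Ryr2 (4.77, others 2.50 to 2.71), and replicate 1 for Sptbn1 (76.5, others 60.3 to 62.0).

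The interaction term passed for 12 genes in footprints and for the erythroid list in RNA. Of these genes, 9 are pseudogenes that share sequence with Hmgb1 and may stand for 1 change. Other splits of the libraries were not fitted for the footprint interaction. In footprints a term for library numbers from 17 up gave 1 gene in all, and a fit of protein-coding genes alone 3. The log2 interaction values were -3.27 for Ahnak, 1.20 for Tgm1 and -1.26 for Hmgb1. They were -1.42 for Gm13577, -1.42 for Hmgb1-ps9, -1.49 for Gm38574, -1.33 for Gm8319, -1.34 for Gm15387, -1.34 for Hmgb1-ps7, -1.35 for Gm5518, -1.31 for Gm21596 and -1.25 for Hmgb1-ps1, all pseudogenes. The erythroid list had a median of -1.96.

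Other splits of the libraries into groups of the same sizes were fitted to ask whether chance can be excluded as the source of each count. For called genes it can be for the treatment effect in RNA of sgScramble mice (1 of 100 splits reached the real count, 2779 genes, highest other 2193), in RNA of sgOgfod1 mice (1 of 100, 2120 genes, highest other 386), in footprints of sgScramble mice (1 of 35, 2847 genes, highest other 122) and in their translation efficiency (1 of 35, 266 genes, highest other 16), and for genotype under vehicle in RNA (1 of 100, 25 genes, highest other 0). It cannot be for genotype under treatment in RNA (6 of 100, 84 genes, highest other 1541). For the RNA interaction the count says nothing, since the real split called 0 genes with edgeR (975 at an unadjusted p under 0.05 and 18 with DESeq2), which all 100 of 100 splits reach. What sets the groups of the split with 1541 genes apart was not tested. Without the pair of RNA libraries standing apart, treated sgScramble replicate 4 and treated sgOgfod1 replicate 3, 394 genes passed for genotype under treatment.

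For called lists at the preset correlation chance cannot be excluded in RNA for treatment in sgScramble (11 of 100 splits, 23 lists, highest other 26) and sgOgfod1 mice (29 of 100, 19 lists, highest other 23), for genotype under vehicle (17 of 100, 12 lists, highest other 17) and under treatment (93 of 100, 7 lists, highest other 25) and for the interaction (69 of 100, 11 lists, highest other 27). Nor can it be for treatment of sgScramble mice in footprints (12 of 35 splits, 12 lists, highest other 17) and translation efficiency (3 of 35, 10 lists, highest other 11). For genotype under vehicle in footprints and translation efficiency the 10 splits are too few for a share under 0.05. The real split gave 331 genes and 17 lists in footprints (highest other 0 and 14) and 17 genes and 13 lists in translation efficiency (highest other 0 and 11).

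Markers of tissue macrophages rose in RNA of treated mice, although cells were sorted for GFP, which host macrophages should lack. The members of the list varied together over the treated libraries within groups, with a mean pairwise correlation of 0.768, at percentile 100 of 10000 random lists of similar expression (highest 0.38). Macrophages among the sorted cells of some treated mice, or leukemia cells bound to or engulfed by them, could give such a shared variation, and so could a macrophage-like state of the leukemia cells in those mice, which this test cannot set apart. The random lists were matched on expression only, and no other marker list was run. A high percentile was thus likely for any list of co-regulated genes. The pair of libraries standing apart is not the whole source, since without them 14 of 15 members were still called higher. What stays open is whether the transcripts come from leukemia cells.

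Footprints on Hmgb1 rose in sgOgfod1 cells under vehicle by 1.20 ± 0.15 (SE) on the log2 scale. All 9 pseudogenes called in the footprint interaction share stretches of 30 bases with the Hmgb1 coding sequence, as do 93 tested pseudogenes, so the several calls may come from 1 change whose reads are spread. A change of the Hmgb1 mRNA is argued against as the whole source, since its RNA log2 fold change was 0.21 ± 0.12, 7.97 of its standard errors below the footprint value. That gap leaves out the error of the footprint value, and it sets RNA of 5 mice per group against footprints of 3. A biological explanation was tested as well, that ribosomes stay longer on runs of acidic residues, of which Hmgb1 holds 1 of 30. The 71 genes with a run of 15 or more had a median footprint change of 0.22. This was at percentile 100 of random sets (median 0.01) and 99.99 of sets matched on coding length. But the 10 splits of the 6 libraries are too few (0.221 above all genes, largest other 0.145). Relative to mRNA the set did not stand out, with 0.134 above all genes in translation efficiency against 0.173 in another split. Treatment of sgScramble cells also moved the set in footprints, by 0.13 above all genes. The acidic-run explanation therefore stays a hypothesis.

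Of 11 genes with higher translation efficiency in sgOgfod1 cells under vehicle, 8 had more than 1591 codons, a length that 5% of genes exceed. A coding length trend of single libraries could give this, with a rank correlation of 0.304 with the efficiency change across genes and of up to 0.371 among the other splits of the 6 mice. Among footprint libraries the trend was negative in all 7 of sgScramble mice (-0.156 to -0.033) and positive in all 5 of sgOgfod1 mice (0.002 to 0.318). After each library's trend was removed among protein-coding genes, 2 of the 8 were still called, Cep350 (1.08 before, 0.63 after) and Fn1 (1.21 and 0.85), while the other calls ended at smaller changes (± SE), Macf1 from 1.19 ± 0.16 to 0.37 ± 0.30, Plec from 1.32 ± 0.24 to 0.69 ± 0.29, Prrc2c from 0.85 ± 0.13 to 0.43 ± 0.13, Sptbn1 from 1.60 ± 0.30 to 1.25 ± 0.26, Syne2 from 1.57 ± 0.22 to 0.82 ± 0.26 and Utrn from 1.25 ± 0.18 to 0.78 ± 0.22. Whether the trend is a bias of the libraries or an effect of Ogfod1 on the translation of long coding regions stays open, as it runs along genotype in the 12 footprint libraries.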

How the results depend on the processing

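Fits without the pair of libraries standing apart, with only mice that have footprints, only protein-coding genes, voom with quality weights, and only genes passing the filter in both assays were chosen after the data were seen. All values are counts of called genes unless said otherwise, in the order treatment effect in sgScramble, treatment effect in sgOgfod1, genotype under vehicle, genotype under treatment, interaction. With every library they were 2779, 2120, 25, 84 and 0 in RNA, 2847, 1503, 331, 289 and 12 in footprints and 266, 24, 17, 14 and 0 in translation efficiency. Values that moved by over 1.5 times are given, and the cause was not tested.

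With DESeq2 size factors the count that moved was 12 for translation efficiency by treatment in sgOgfod1, where the Ogfod1 change under vehicle was -1.63 and lost its call. The median of all genes shifted by -0.12 in the interaction of translation efficiency. Of the named genes 274 of 277 in RNA, 291 of 293 in footprints and 66 of 74 in translation efficiency kept direction and call, and of called lists 71 of 72, 85 of 85 and 35 of 43. No low-count filter gave 1403 (treatment in sgOgfod1) and 16 (genotype under vehicle) in RNA, 1012, 929 and 260 (genotype under vehicle, under treatment, interaction) in footprints, and 817, 276, 401, 341 and 173 in translation efficiency. It gave 12 called lists for genotype under treatment in RNA and 7 for genotype under vehicle in translation efficiency, where DESeq2 size factors gave 8. The DESeq2 test gave 3287, 115, 575 and 18 in RNA (from treatment in sgOgfod1 on), 610, 582 and 52 in footprints (from genotype under vehicle on) and 1077, 75, 174, 162 and 65 in translation efficiency. Leaving out mitochondrially encoded genes moved no count by over 1.5 times.

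The term for library numbers from 17 up gave 1646 in RNA for treatment in sgScramble, and in footprints 1503, 6, 2 and 1 for both treatment effects, genotype under treatment and the interaction. Both treated sgOgfod1 footprint mice have such numbers. Only the 2 groups compared gave 497 and 13 in RNA for genotype and 206, 605 and 94 in footprints from treatment in sgOgfod1 on. Without the pair of libraries standing apart RNA had 3877, 88 and 394 from treatment in sgOgfod1 on, and with only footprint mice 850, 39 and 587. Without that pair 60 called RNA lists kept direction and call and 12 lost their call. Protein-coding genes alone gave 941 and 3 in footprints (treatment in sgOgfod1, interaction) and 883, 67, 131, 92 and 8 in translation efficiency. Voom with quality weights gave 5687, 3691, 426 and 314 in RNA, 782, 829, 52 and 7 in footprints from treatment in sgOgfod1 on, and 638 and 32 in translation efficiency (treatment in sgScramble, genotype under treatment). Genes passing in both assays gave 699 and 28 (treatment in sgScramble, genotype under vehicle). Translation efficiency without the mouse block gave 56, 7, 1 and 7 over the matched mice and 13, 5, 2 and 0 over all libraries, where 1 named gene, Clec4a3 for treatment in sgOgfod1, changed sign to -0.77.

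The block on replicate numbers gave 1479, 1409 and 29 in RNA (both treatment effects, genotype under treatment) and 94, 122 and 57 in footprints (genotype under vehicle, under treatment, interaction). Same numbers in different groups do not pair mice, with a median correlation of -0.013 over 31 RNA pairs (8 over 0.1) and -0.014 over 11 footprint pairs (1 over 0.1), so the block says little.

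With an estimated correlation the called lists were 0, 2, 2, 0 and 1 in RNA and 0 in each comparison of footprints and of translation efficiency. The correlation of RNA and footprint fold changes over genes with at least 10 counts was 0.615, 0.577, 0.487, 0.431 and 0.348.

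Leaving out 1 library at a time, counts in RNA ran from 1834 to 3086, 1344 to 2454, 3 to 17, 48 to 376, and 0 to 0. In footprints they ran from 1365 to 2488, 848 to 1295, 70 to 335, 116 to 505 and 1 to 93, and in translation efficiency from 49 to 394, 10 to 23, 4 to 26, 8 to 42 and 0 to 3. Where this leaves 1 treated sgOgfod1 footprint mouse, it is assumed to vary like the other groups. The Ogfod1 log2 value ran in RNA from -0.17 to 0.04, -0.36 to -0.06, -1.12 to -0.99, -1.37 to -1.08 and -0.30 to -0.00, in footprints from -0.04 to 0.12, -0.64 to 0.36, -2.83 to -2.38, -3.36 to -2.36 and -0.68 to 0.32, and in translation efficiency from -0.20 to 0.07, -0.51 to 0.71, -1.91 to -1.36, -1.98 to -0.89 and -0.39 to 0.79. Over these fits 2791 gene values of the named RNA genes kept their call and 413 lost it, 1372 and 483 in footprints, and 263 and 210 in translation efficiency.

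Footprint libraries held a median of 9.25 M counts against 56.1 M in RNA, yet simulated 2-fold changes by treatment in sgScramble were called in 71.6% of footprint genes, 31.3% of RNA genes and 2.99% in translation efficiency. What depth adds to these limits was not tested. Shallow libraries were to be left out, but none met that limit.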

Other observations

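Neither the list of genes that handle the drugs given nor that of adhesion and homing passed for treatment of sgScramble cells (adjusted p = 0.874 and 0.826 in RNA, 0.97 and 0.465 in footprints), and single members went both ways. Of the drug list 4 of 19 were higher and 2 lower in RNA and 2 of 18 higher and 3 lower in footprints, and of the adhesion list 3 of 18 were higher and 2 lower in RNA and 2 of 15 higher and 5 lower in footprints. In RNA the cytarabine deaminase Cda rose by 2.65 ± 0.75 (SE) on the log2 scale and the hydrolase Samhd1, which degrades the active triphosphate of cytarabine, by 1.87 ± 0.43 (edgeR adjusted p = 0.0215 and 0.00552). The doxorubicin target Top2a fell by 1.05 ± 0.24 (adjusted p = 0.0059). Footprints on the efflux pump gene Abcb1b, which exports doxorubicin, fell by 3.10 in sgScramble and 3.55 in sgOgfod1 cells (adjusted p = 4.1e-05 and 0.00126), and also by genotype under vehicle, by 1.27 (adjusted p = 0.029). Of the adhesion list, the integrin Itga4 fell by 1.06 ± 0.26 in RNA (adjusted p = 0.00852), and footprints on the chemokine receptor Cxcr4 fell by 0.71 (adjusted p = 0.00171).

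A hypothesis was that a diet without leucine, isoleucine and valine lowers the footprints per mRNA on coding regions rich in their codons, which make up 20.6% of codons in the median gene. Across 10974 genes the share of these codons had a rank correlation of -0.051 with the change of translation efficiency by treatment in sgScramble cells. Of the 35 splits of these 7 mice 9 gave a value as low, and the others ran from -0.077 to 0.09, so the test does not decide. By amino acid, for which no outcome had been predicted, the correlations were -0.158 for leucine, 0.211 for isoleucine and -0.065 for valine codons. A second hypothesis, that such coding regions respond differently without Ogfod1, met a correlation of 0.067 with the interaction and is likewise undecided. A count of footprints per gene cannot see stalling at single codons, which would need reads by position.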
